A study of Bradyrhizobium diazoefficiens USDA 110 with 6 samples.

How the data were processed

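RNA of the soybean symbiont Bradyrhizobium was hybridised to 2-colour arrays, on which cDNA from H2O2-grown and from untreated cells competes for the same probes. Per the labels, 3 independent biological replicates were each measured on 2 arrays, the second with the dyes swapped, which gives 6 arrays. RNA was extracted with hot phenol, copied with random hexamers and coupled to Cy3 or Cy5, per the labels' protocols.

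The deposited table holds 1 log ratio per probe and array. The scanner software, the background correction, the normalization, the reason for empty cells and the base of the logarithm are not given in the sources used here. The values were read as log2 ratios, the usual form for deposited 2-colour values of this range, but the base stays unknown. The direction is not recorded either: H2O2-grown over untreated is likely, from the order of the sample titles, and every sign and every fold rests on that reading. All pairs of arrays correlated positively, so the authors had already turned the swapped arrays and no sign was changed here. Array medians lay between -0.0152 and 0.0527. Among the 3419 probes with a value on all 6 arrays, the sum over the arrays labelled with H2O2 in Cy5 equalled the sum over those with H2O2 in Cy3 in 3419, within a tolerance of 1e-06. A mean difference between the labelled dye orientations had therefore been taken out of each of these probes before deposit. This does not move the mean of a dye-swap pair, but it hides part of the dye effect, and a fit with the labelled dye calls no dye effect by construction.

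Of 8480 probes, 8462 were found in the platform's probe table and 18 were not. No probe had several genes, and 1469 had a symbol beyond the locus tag. That table is old, gives no product names and no coordinates, and its tags could not be joined to the other annotation supplied, which was not used. Probes with values on all 6 arrays were kept and probes of one locus averaged, which left 3373 genes, 738 of them with a symbol. Of the 41 genes averaged over several probes, 16 had probes of opposite sign and 6 had probes over 1 log2 unit apart. Each dye-swap pair was averaged to 1 value per replicate. The mean of the 3 replicates was tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The SD given with a gene is that of its 3 replicate means. For arrays the number of replicates limits the precision, and no spot intensities were analysed here.

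Gene lists were written before the data were examined, as patterns on symbols, and 23 were fixed. The 13 lists with at least 5 measured genes were tested with limma's camera, each against all other genes, with a preset correlation of 0.01 between genes and adjustment over the lists. An estimated correlation was the alternative. With it camera tests on the residual degrees of freedom of the 3 replicates, far fewer than at the preset correlation. A list can then lose the call whatever its correlation, so a lost call there cannot decide whether the list is shifted. Genes to name were also fixed by rule: the 10 largest increases and 10 largest decreases among called genes with the same sign on all 6 arrays, the 3 largest each way whatever the annotation, all measured genes of the peroxide detoxification list, and up to 4 members of each other list. Called members with the largest change came first. The rule was to leave out products of unknown function from the first part. Without product names, genes with no symbol beyond the locus tag were left out there instead. Genes named beyond the rule are marked in the text as chosen after their values were seen.

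The test was tried on simulated data of 3373 genes, 200 of them changed, for the comparison of H2O2 against untreated with 3 replicates. It recovered 10.4% of the genes changed by 0.5 log2 units, 56.7% of those changed by 1 and 95.5% of those changed by 2, with 5 false calls among 113. The simulated noise was normal and independent between genes, with each gene's own SD. It held no dye bias and no shift shared by the genes of a replicate. The share of false calls is therefore no measure of the error among the real calls. Alternatives planned before the data were examined were leaving out each replicate, a fit of all arrays with a dye term and the replicate as a random effect (statmod 1.5.0), 1 dye orientation alone, centring, scaling to one median absolute deviation (limma's normalizeMedianAbsValues), a looser filter on missing values (both arrays in at least 2 replicates), robust variance moderation, other thresholds, rank-based camera and camera with an estimated correlation. Added after seeing the data were each probe on its own, leaving out genes whose paired arrays differ by over 1, and a dye term that follows the dye-biased probes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.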

Results

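The 6 arrays compared cells of Bradyrhizobium diazoefficiens, a nitrogen-fixing soil bacterium that nodulates soybean, grown with 0.3 mM H2O2 throughout growth, with cells grown without it. The comparison asks how gene expression differs after prolonged exposure to peroxide. Each of 3 biological replicates was measured on an array and its dye swap. The arrays had values for different shares of the 8480 probes: 59.6% and 41.0% in replicate 1, 85.3% and 85.2% in replicate 2, and 67.7% and 83.6% in replicate 3. Across the probes with 6 values, which are not independent replicates, the arrays of a pair correlated with r = 0.859, 0.964 and 0.791 in replicates 1, 2 and 3, and arrays of different replicates with r between 0.596 and 0.828. The array of replicate 1 with H2O2 labelled Cy5 had r = 0.812 with that of replicate 3 labelled Cy3, above the 0.791 within replicate 3. With that of replicate 3 labelled Cy5 it had r = 0.657. Values below are mean log2 ratios ± SD (n = 3 biological replicates). Positive values likely mean higher expression in H2O2-grown cells, although neither the direction nor the base of the logarithm is recorded.

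In cells grown with H2O2, 37 of 38 measured ribosomal protein genes and 5 of 8 translation factor genes fell. Both lists passed the test at the preset correlation. Neither was called by camera with an estimated correlation (adjusted p = 0.227 for each). The few degrees of freedom that 3 replicates leave in that setting keep it from deciding. Among genes with values on all 6 arrays, the largest decrease was in tuf (bll5402), which encodes elongation factor Tu, at -4.96 ± 0.48 or 31.2-fold lower (adjusted p = 9.22e-06). The next were the ribosomal protein genes rpsQ (bsl5391, -4.61 ± 0.28), rpsJ (bll5401, -4.60 ± 0.29), rpsG (bll5404, -4.34 ± 0.43) and rplC (bll5400, -4.24 ± 0.32). Among genes with values on all 6 arrays the increases were smaller, with bll6220, a gene without a symbol, highest at 2.55 ± 0.28 (adjusted p = 6.86e-05). In all, 916 of the 3373 genes tested passed the threshold, 384 of them higher and 532 lower, and 898 of the 916 had the same sign on all 6 arrays. At least 2-fold changes were found for 271 of them, 101 higher and 170 lower. Among called genes with a symbol, 62 were higher and 217 lower. The count of 916 fell to 463 without replicate 1, the replicate with the fewest values, and the 384 higher genes became 201 without replicate 1 and 201 without replicate 2, while the 532 lower genes became 262 without replicate 1 and 354 without replicate 3. With genes measured on both arrays of at least 2 replicates, 692 genes were higher and 619 lower.

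For 66 genes the arrays of replicate 1 differed by over 1 log2 unit, against 12 genes in replicate 2 and 75 in replicate 3, and 5 of the 66 were called. With each gene signed so that the Cy3 array of replicate 1 is the higher, the median mean of the 66 genes was 0.07, 0.98 and 0.06 in replicates 1, 2 and 3. In a fit of all arrays with a dye term that follows the signs of these genes on the arrays, added after seeing the data, the dye term passed the threshold for 348 genes. That fit called 864 genes changed with H2O2, of which 778 were among the 916.

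**Figure D1:**
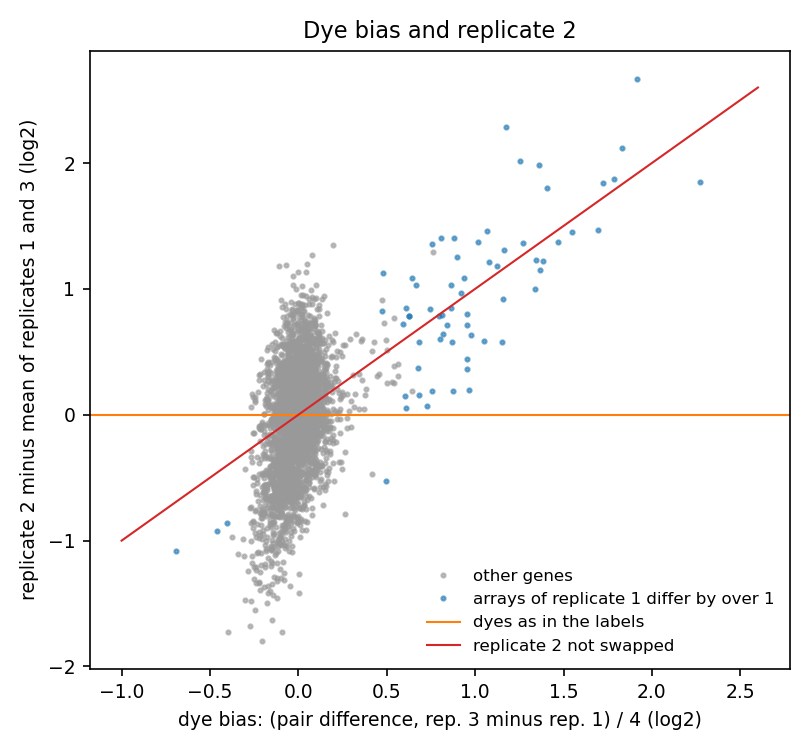
Each point is a gene, with the dye bias estimated from the pair differences of replicates 1 and 3 (horizontal axis, log2) against the mean of replicate 2 minus the mean of replicates 1 and 3 (vertical axis, log2). Blue points are the 66 genes whose replicate 1 arrays differ by over 1, and lines show dyes as in the labels (orange) and replicate 2 not swapped with replicates 1 and 3 swapped in opposite ways (red). The blue points have a median excess of 0.944 in the direction of the bias.

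**Figure D2:**
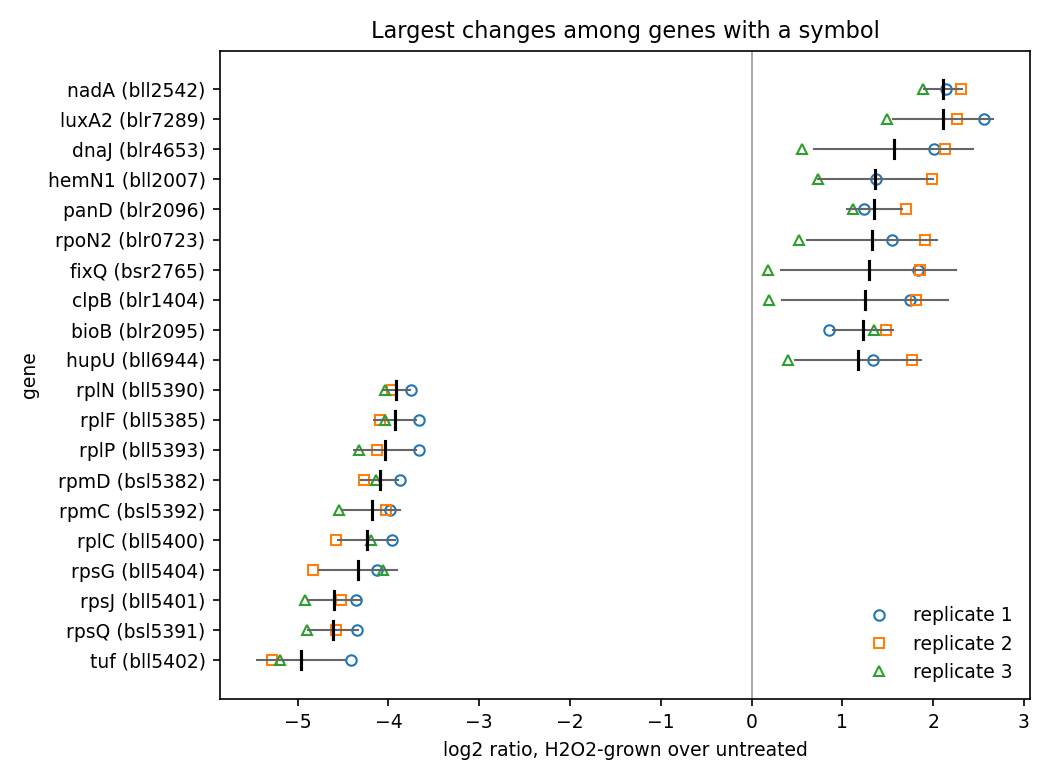
Log2 ratio of H2O2-grown over untreated cells (horizontal axis) for the 10 largest increases and 10 largest decreases among called genes with a symbol (vertical axis). Open symbols are the 3 biological replicates, black ticks their mean and grey lines the mean ± SD, with tuf lowest at -4.96 and nadA highest at 2.11.

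Of 38 measured ribosomal protein genes, 37 fell and none rose, with a median of -2.40. The largest decreases included rpmC (bsl5392, -4.19 ± 0.32), rpmD (bsl5382, -4.10 ± 0.20), rplP (bll5393, -4.04 ± 0.34), rplF (bll5385, -3.93 ± 0.23) and rplN (bll5390, -3.92 ± 0.15). The gene that was not called was rpsU (bsr7117, -0.23 ± 0.66), named after its value was seen. Camera gave an adjusted p of 2.17e-33 for the list, and adjusted p = 0.227 with an estimated correlation. Adjusted over the list alone, 37 genes were called as well. Of 8 translation factor genes, 5 fell: tuf, infB (bll0783, -1.42 ± 0.15) and infA (bsl1446, -1.33 ± 0.23), which encode an elongation factor and initiation factors, and tsf (bll4860, -1.40 ± 0.11) and efp (bll4386, -1.37 ± 0.18), which encode elongation factors. Of these infA was named after its value was seen. The list had an adjusted p of 0.000221, and adjusted p = 0.227 with an estimated correlation, with 6 called when adjusted over the list alone.

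Of 37 genes of aerobic respiration and ATP synthesis, 20 fell and 2 rose, with a median of -0.51. All 6 measured atp genes, which encode ATP synthase, fell, among them atpA (bll0442, -2.18 ± 0.13), atpC (bsl1187, -2.17 ± 0.24), atpB (bll1185, -2.10 ± 0.10) and atpD (bll0440, -1.93 ± 0.14). The call of atpH (bll0443, -0.83 ± 0.65, adjusted p = 0.0384), named after its value was seen, is less certain. It was among the 66 genes whose replicate 1 arrays differ by over 1. Like the other called genes among these 66, atpH did not have the same sign on all 6 arrays. Its replicate means were -1.56, -0.30 and -0.64. The genes that rose were cycC (bll5913, 0.61 ± 0.14) and cycL (blr3128, 0.70 ± 0.52), of c-type cytochromes or their assembly by their symbols, named after their values were seen. The list's adjusted p was 0.000114, and adjusted p = 0.227 with an estimated correlation, with 26 called when adjusted over the list alone. Of 6 genes of the tricarboxylic acid and glyoxylate cycles, 3 fell: gltA (blr4839, citrate synthase, -1.39 ± 0.08), mdh (bll0456, malate dehydrogenase, -1.25 ± 0.10) and icdA (blr5747, isocitrate dehydrogenase, -0.73 ± 0.12). This list had an adjusted p of 0.0101, and adjusted p = 0.586 with an estimated correlation, with 3 called when adjusted over the list alone. Without replicate 1, icdA was no longer called (-0.66, adjusted p = 0.0691).

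Chaperone and protease genes moved both ways. Of 26 measured, 10 fell and 3 rose, with a median of -0.32. The groEL genes blr7533 (-1.73 ± 0.13) and blr5626 (-1.19 ± 0.20), which encode the large chaperonin subunit, fell. The genes that rose were dnaJ (blr4653, 1.56 ± 0.88), clpB (blr1404, a disaggregase, 1.25 ± 0.92) and hspH (bll0729, 0.57 ± 0.33), the last named after its value was seen. In replicate 3 dnaJ stood at 0.55 and clpB at 0.20. The other dnaJ genes, bll0184 (0.03 ± 0.37) and blr2626 (-0.27 ± 0.11), and another hspH (blr6571, -0.15 ± 0.25) were not called. The gene dnaK (blr0678, -0.70 ± 0.07) fell. These too were named after their values were seen. The list had an adjusted p of 0.0231, and adjusted p = 0.586 with an estimated correlation, with 15 called when adjusted over the list alone. Without replicate 1 the list was no longer called (adjusted p = 0.161), nor was clpB (1.01, adjusted p = 0.105). Without replicate 2 clpB (0.97, adjusted p = 0.125) and the dnaJ gene blr4653 (1.28, adjusted p = 0.0583) were not called.

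Of 41 measured genes for microaerobic and anaerobic respiration, 13 rose, 3 fell and 25 were not called, with a median of 0.25. The list had an adjusted p of 0.00991, and adjusted p = 0.586 with an estimated correlation. Among those that rose were hemN1 (bll2007, 1.36 ± 0.63), which encodes an oxygen-independent haem synthesis enzyme, fixQ (bsr2765, 1.29 ± 0.96), for a subunit of the high-affinity cbb3 oxidase, hupU (bll6944, 1.17 ± 0.69), of the hydrogen-sensing hydrogenase, and the regulator gene fixK (bll2109, 1.07 ± 0.33). The genes that fell, named after their values were seen, were hemN (bll0672, -0.53 ± 0.13), another fixK (bll7696, -0.51 ± 0.28) and hupA (bll6175, -0.51 ± 0.14), a symbol also used for the DNA-binding protein HU. The other fixK genes, bll2757 (-0.33 ± 0.36) and bll6061 (-0.28 ± 0.13), were not called. Of 4 measured cbb3 oxidase genes (fixNOQP) 2 rose, while fixN (blr2763, -0.06 ± 0.58) and fixO (blr2764, 0.78 ± 0.98) were not called. These too were named after their values were seen. The list mean was 0.50, 0.40 and 0.04 in replicates 1, 2 and 3. Adjusted over the list alone, 16 were called. Without replicate 1 the list (adjusted p = 0.0814), fixQ (1.02, adjusted p = 0.109) and hupU (1.09, adjusted p = 0.0621) were no longer called, nor were fixQ (1.01, adjusted p = 0.131) and hupU (0.87, adjusted p = 0.0607) without replicate 2.

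**Figure D3:**
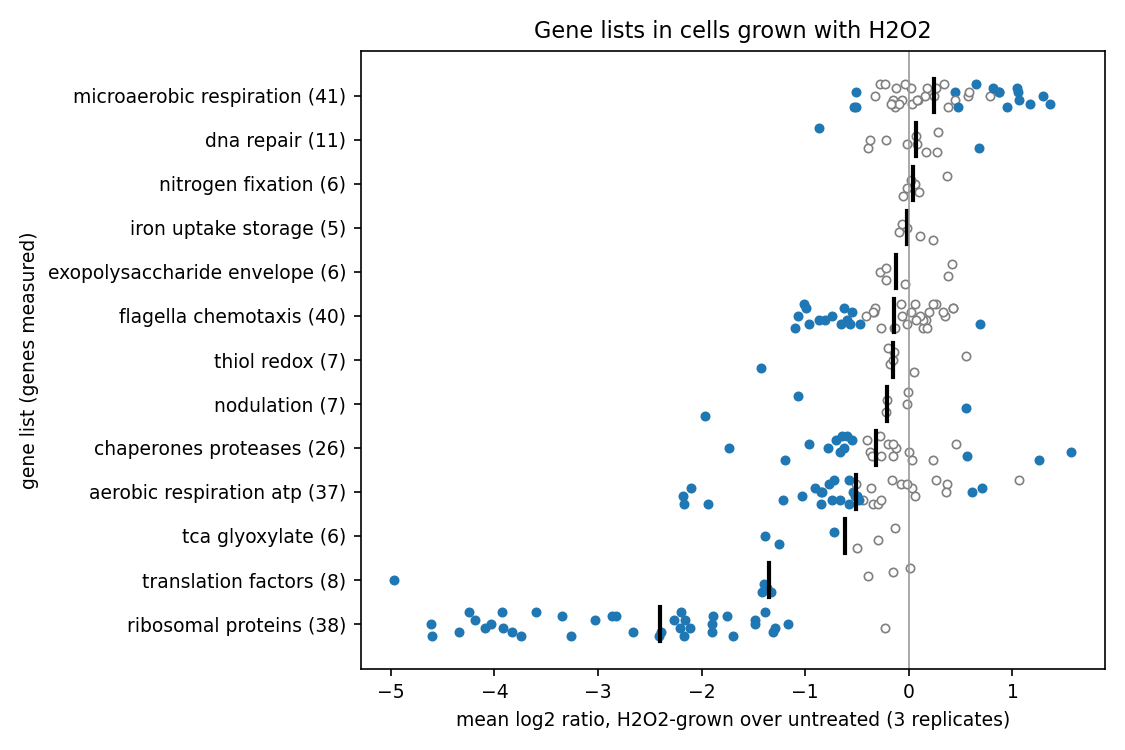
Mean log2 ratio of H2O2-grown over untreated cells (horizontal axis, 3 replicates) for each measured gene of the 13 tested lists (vertical axis, genes measured in parentheses). Filled points are called genes, open points are not called, and black bars are list medians, from -2.40 for ribosomal proteins to 0.25 for microaerobic respiration.

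Other large increases were in nadA (bll2542, quinolinate synthase of NAD synthesis, 2.11 ± 0.21, adjusted p = 0.000110), luxA2 (blr7289, 2.11 ± 0.55), panD (blr2096, of pantothenate synthesis, 1.35 ± 0.31) and bioB (blr2095, biotin synthase, 1.23 ± 0.33). Of the sigma factor and stress regulator list, 4 genes were measured and not tested as a list. The gene rpoN2 (blr0723, 1.33 ± 0.72) and the heat-shock sigma factor gene rpoH2 (blr7337, 0.59 ± 0.30) rose, sigA (bll7349, -0.66 ± 0.09) fell, and rpoN1 (blr1883, 0.50 ± 0.30, adjusted p = 0.0535) was not called. Adjusted over the list alone, 4 were called. The call of rpoH2 was lost without any 1 of the replicates (adjusted p = 0.0590, 0.0787 and 0.0804 without replicates 1, 2 and 3), and that of sigA without replicate 1 (0.0614) or replicate 3 (0.0586), while rpoN1 was called without replicate 3 (0.0406).

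The peroxide detoxification list was matched on symbols alone, so catalase or peroxidase genes without a symbol are not covered, and its measured genes include no catalase. None of its 4 measured genes was called by limma, at the adjusted threshold, over the list alone or at an unadjusted p under 0.05, where the count was 0. The superoxide dismutase gene sodF (bll7774) had 0.40 ± 0.68 with an adjusted p of 0.282, and it was among the 66 genes whose replicate 1 arrays differ by over 1. Its arrays had opposite signs in replicate 1 (-1.04 and 1.36) and in replicate 3 (1.42 and -1.66), and the same sign in replicate 2 alone (0.83 and 1.51). The methionine sulfoxide reductase genes msrA had -0.24 ± 0.10 (blr0834) and 0.26 ± 0.31 (blr7043), and the organic hydroperoxide resistance gene ohr (blr1196) had 0.01 ± 0.10. The alkyl hydroperoxide reductase genes ahpC and ahpD had a value on 0 arrays, so they were not measured. The gene bcpB (bll5069), a peroxiredoxin symbol outside the list and named after its value was seen, had 0.34 ± 0.21 (adjusted p = 0.126). Of 7 thiol and redox genes, gst (bll2509, a glutathione transferase symbol, -1.43 ± 0.07) fell and none rose (list adjusted p = 0.633), with 1 called over the list alone. Among 11 DNA repair genes, lexA (blr4826, the SOS repressor, -0.86 ± 0.22) fell and uvrB (blr7431, excision repair, 0.68 ± 0.44) rose, with 2 called over the list alone and a list adjusted p of 0.991, where the median was 0.07 and the mean -0.03. The call of uvrB was lost without replicate 2 (0.55, adjusted p = 0.131) and without replicate 3 (0.54, adjusted p = 0.133). Of 5 iron uptake and storage genes 0 were called, also at an unadjusted p under 0.05 or over the list alone, with irr (bll0768) at 0.24 ± 0.49. That list's adjusted p was 0.878, with a median of -0.02 and a mean of 0.03.

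Of 40 flagellar and chemotaxis genes, 14 fell and 1 rose, with a median of -0.14, and the list was not called (adjusted p = 0.0899), though it was without replicate 3 (0.0455). With an estimated correlation and all replicates, camera gave the list an adjusted p of 0.586. Of 12 che genes, 11 fell, among them cheA (blr2343, -1.10 ± 0.34), cheY (blr2194, -1.07 ± 0.23), another cheY (blr2342, -1.01 ± 0.23) and cheR (blr2196, -0.99 ± 0.10). Of the other 28 genes 3 fell and 1 rose, the latter flgD (bll6853, 0.69 ± 0.50), a hook assembly gene named after its value was seen. The list was divided in this way after the values were seen, and the difference between the parts was not tested on other data. Adjusted over the list alone, 15 genes were called.

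Of 7 nodulation genes, nodQ (bll1475, -1.97 ± 0.09), whose product activates sulfate, and nodA (blr2025, an acyltransferase of Nod factor synthesis, -1.07 ± 0.13) fell, and nodW (bll1714, a response regulator, 0.55 ± 0.19) rose. The arrays of nodA lay over 1 log2 unit apart in replicate 2 (-1.54 and -0.30) and differed in replicate 3 too (-0.67 and -1.53), all below 0, and it was not called in the fit of all arrays with the labelled dye as a term and the replicate as a random effect (adjusted p = 0.0614). The list's adjusted p was 0.362, with 3 called over the list alone. The call of nodW was lost without replicate 1 (0.55, adjusted p = 0.130) and without replicate 3 (0.45, adjusted p = 0.148). Of 6 nitrogen fixation genes 0 were called, also at an unadjusted p under 0.05 or over the list alone, with fixX (bsr1775) farthest from 0 at 0.37 ± 0.31 (list adjusted p = 0.633). Of 6 exopolysaccharide and envelope genes limma called 0, also over the list alone, against 2 at an unadjusted p under 0.05, with exoB (blr7578) at 0.42 ± 0.24 (list adjusted p = 0.878, median -0.13, mean 0.01).

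The remaining lists had under 5 measured genes and were not tested. Of 2 efflux genes, emrA (bll6622, -0.50 ± 0.12) fell, a call lost without any 1 of the replicates (adjusted p = 0.172, 0.0617 and 0.0725 without replicates 1, 2 and 3). Of 2 carbon fixation genes 0 were called over all genes and 1 over the list alone or at an unadjusted p under 0.05, cbbL (blr2585, 0.44 ± 0.26). The type III secretion gene rhcN (blr1816, 0.03 ± 0.18) and betB (blr3776, -0.13 ± 0.12), of compatible solute synthesis, were the 1 measured gene of their lists and were not called. The 4 lists for iron-sulfur assembly, hopanoid synthesis, arabinose and gluconate catabolism, and transposases had 0 measured genes.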

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

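Without 1 replicate, which leaves fewer samples, 463 to 676 genes were called (main count 916), with 201 to 322 higher and 262 to 460 lower; the lowest total came without replicate 1, and of its 463 genes 454 were among the 916. The share of higher genes was 41.9% and ranged from 30.4% without replicate 2 to 47.6% without replicate 3 (58.1%, 69.6% and 52.4% if the ratio runs the other way). A threshold of 0.01 called 407 genes, and a size of 1.5-fold in place of 2-fold gave 689 genes in place of 271, both by construction. With both arrays in at least 2 replicates, 5603 genes were tested, and 692 were higher against 384 and 619 lower against 532. The share of higher genes was 52.8% (47.2% with the ratio turned). Of the added genes 290 were called higher and 71 lower, so the number tested alone does not account for the rise in higher genes. With an estimated correlation 0 lists were called against 6. That setting also tests on the residual degrees of freedom of the 3 replicates, so the 0 cannot decide whether the lists are shifted. In the aerobic respiration and translation factor lists the estimated correlation (-0.0145 and -0.0188) lay below the preset 0.01. This argues against a stronger correlation between genes as the cause in these lists, and leaves the fewer degrees of freedom. In the other called lists the estimate was higher, from 0.136 to 0.279. There the higher correlation and the fewer degrees of freedom both raise the p-value, and their shares were not separated. All other settings run for the total and the 2-fold count stayed within 1.5 times, including the dye term added after seeing the data (864 genes, 778 of them among the 916). The arrays of either dye orientation alone gave the same mean ratios by construction, so their counts (695 and 661) speak only of the spread. Of 47 named genes that were called, 10 lost the call without 1 replicate. Over the alternatives for named genes, 576 values stayed on their side of the threshold, 27 lost a call, 5 gained one and none changed sign with a call. For the lists these were 108, 8 and 1. The main test is already a paired analysis, because both conditions were hybridised on every array and each ratio is paired. Missing values limit the genes tested: 891 probes had no value on any array, and signal over background was not analysed here.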

Other observations

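Apart from the looser filter on missing values, which was planned, the tests in this part were chosen after the data were seen. Of 17 stems with at least 5 measured genes outside the fixed lists, 4 passed camera at the preset correlation, all lower, and each lost the call with an estimated correlation (adjusted p = 0.562). That setting has few degrees of freedom with 3 replicates, so the lost calls cannot decide whether these stems are shifted. Of 5 sec genes, for protein export, 4 fell (adjusted p = 0.00315, and adjusted p = 0.562 with an estimated correlation), among them secE (-1.67 ± 0.27) and secD (-1.32 ± 0.18). Of 6 fts genes, 4 fell (adjusted p = 0.0218, likewise 0.562), among them the cell division genes ftsA (-1.46 ± 0.41) and ftsZ (bll6596, -1.29 ± 0.32). Of 8 fab genes, for fatty acid synthesis, 5 fell (adjusted p = 0.0389), and of 13 ctp genes 9 fell (adjusted p = 0.00246). For fab and ctp too it was 0.562 with an estimated correlation. The gene cysD (bll1476), for sulfate activation, fell to -3.11 ± 0.29, beside its neighbour in number nodQ (bll1475, -1.97 ± 0.09).

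Genes that missed values on some arrays leaned the other way. The looser filter added 2230 genes, of which 361 were called, 290 higher (80.3%, or 19.7% if the ratio runs the other way) and 71 lower. Among them bll3387 (3.94) and bll3381 (3.77), which have no symbol, were higher than any gene of the main test, while rplI (-4.22) and rpsC (-4.03) were ribosomal protein genes among the lowest. These means rest on 2 replicates, against 3 in the main test. The genes bll3387, bll3381 and rplI lacked a replicate 1 mean, and rpsC lacked that of replicate 3. On the arrays, 1453 probes missed a value only on the Cy3 array of replicate 1, so many added genes rest on replicates 2 and 3. Of these probes 0 had equal sums over the 2 complete pairs, unlike the probes of the main test. Their lean may therefore differ from the main test for reasons other than expression.

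Turning the sign of 1 replicate at a time gives 4 splits, too few for a share under 0.05. The real signs called 916 genes and 271 at least 2-fold, in each case the only 1 of the 4 splits with as many, and the highest other split called 0 of either. For lists, 2 of the 4 splits gave as many, with 6 for the real signs and 6 for the highest other, replicate 3 turned.

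For 66 genes the 2 arrays of replicate 1 differed by over 1 log2 unit, and in 63 of them the arrays had opposite signs. A change with H2O2 in all replicates is argued against, since the medians in the direction of the bias were 0.07, 0.98 and 0.06 in replicates 1, 2 and 3 (test value 0.0580). A dye bias of these probes with the dyes as in the labels would cancel in every pair mean, yet replicate 2 exceeded the others by a median of 0.944. A candidate explanation is dye bias with dyes placed otherwise than in the labels, with replicate 2 not swapped and replicates 1 and 3 swapped in opposite ways (their pair differences had opposite signs in 66 of the 66 genes, which the equal sums over the labelled dyes partly fix): the excess of replicate 2 should then follow the pair differences of replicates 1 and 3 with a slope of 1, and the slope was 1.18 (95% interval 0.975 to 1.39) over the 66 genes, which were chosen by a difference that enters the predictor, and 1.23 (1.15 to 1.30) over all genes, above 1. A change in the cultures of replicate 2 alone could not give the 2 arrays of replicate 1 opposite signs, as in 63 of the 66 genes. It stays open as a source of the excess of replicate 2. Of the 66 genes 5 were called. Over all 3373 genes tested, the 66 included, a dye term with the sign pattern set by these 66 passed the threshold for 348.

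Ribosomal protein genes had the lowest median of the 13 tested lists, with 37 of 38 called. A dye effect is argued against by a mean of -2.61 on the 2 arrays where the biased probes turn sign, against -2.74 on the other 4. A shift of whole arrays by the normalization is argued against since the list mean minus the median of the other genes was -2.46 on the array where it was nearest to 0, and a change in 1 gene cluster by a mean of -2.10 over the 16 genes outside the largest ribosomal cluster by locus number, of which 15 were called. A slower growth of the H2O2 cultures, or a later growth stage at harvest, may lie behind the difference and was not tested, and neither was a bias of the normalization at high intensity, since neither growth nor intensities were analysed here.

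Of the 13 microaerobic genes that rose, 12 were lower in replicate 3 than in the mean of replicates 1 and 2, with medians of 0.34 and 1.20. Compressed ratios on the arrays of replicate 3 are argued against as the whole source. The 532 genes that fell kept 0.909 of their median there, and the 371 other genes that rose kept 0.841, against 0.285 for the 13 microaerobic genes. All were called with replicate 3 included, which favours genes that keep their size there. The SD over probes was lowest on the arrays of replicate 3 (0.588 and 0.556), so some compression stays possible. A dye effect on 1 array of replicate 3 is argued against by a median difference of 0.114 between its arrays, against a gap of 0.848. A lower oxygen supply in the H2O2 cultures than in the untreated cultures of replicates 1 and 2 may be the source of the gap, as an untested biological explanation.

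Neighbouring genes, taken by consecutive locus numbers and without ribosomal protein genes, had similar ratios when their tags named the same strand (r = 0.478 over 1113 pairs) and less so on opposite strands (r = 0.122 over 513 pairs), correlations across genes, which are not independent replicates. The difference of 0.356 had a two-sided permutation p of 1e-04, the smallest the shuffles can give, and is consistent with neighbours transcribed together.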
